A study of Homo sapiens with 11 samples.

How the data were processed

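Messenger RNA levels of MCF-7 cells, a human breast cancer line that carries oestrogen receptor, were measured on 11 single-colour Agilent arrays, 1 RNA sample per array. Cells were given plumbagin (2 arrays) or acetyl plumbagin (3 arrays) at 10 µM for 6 h. The labels name a separate untreated set for each compound (3 arrays each), called the plumbagin controls and the acetyl plumbagin controls below. Per the labels, 150 ng of total RNA per sample was labelled with Cy3 by linear amplification. Per the labels, 1 further plumbagin RNA was left out of the series because its integrity was poor.

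The scanned images were read with Agilent Feature Extraction 10.7.1.1, and per the file headers each scanner file holds the fluorescence intensity of 44495 spots, of which 43118 belong to genes. The processed signal is that intensity after background subtraction and detrending within the array, per the file headers, with no scaling between arrays. The deposited value table holds the background-subtracted intensity: 489203 of 489203 values lay within 0.001 of that column of the scanner files. The deposited table is therefore on a linear scale and not centred, with medians of 14.2 to 264 per array and 1.9% to 18.8% of values below 0.

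Values analysed here were log2 processed signals minus the log2 75th percentile of the gene spots of the same array. Spots with an outlier mark were dropped and the other spots of a probe were averaged, which left out 248 probes that lacked a value on some array. Of the 33879 probes left, 24826 matched 1 symbol by transcript accession in the RefSeq gene table of GRCh38.p14. The array design was annotated on hg19, and no coordinate is used here. For each gene the probe with the highest mean signal over all arrays was kept. A gene was tested where its probe was well above background on every array of at least 1 group, which gave 17648 genes, 13696 with a symbol and 3952 known by accession or probe only.

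All 11 arrays were fitted with 1 mean per group in limma 3.58.1 (R 4.3.3), with moderated tests and Benjamini-Hochberg adjustment over the 17648 genes, and a gene was called where the adjusted p was under 0.05. The contrasts were each compound against its own controls, the difference between those 2 responses, and the 2 untreated sets against each other. The prior had 1.86 degrees of freedom and the total was 8.86. The median standard error was 0.24 for the plumbagin response, 0.22 for the acetyl plumbagin response and 0.32 for their difference. On simulated data with 200 changed genes, 29% of changes of log2 1 and 69% of changes of log2 2 were called in the plumbagin contrast, with 5 false among 103 calls. For acetyl plumbagin these shares were 36% and 74%, with 6 false among 116 calls. The simulation drew independent normal noise for each gene and array, with no slide effect and no correlation between genes. Its false calls therefore do not measure errors from slide or array brightness in the real data. The number of arrays limits the precision of every value.

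Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. The 22 lists covered NRF2 targets, heat shock chaperones, metallothioneins, endoplasmic reticulum chaperones, ATF4 targets, p53 targets, oestrogen-induced genes, luminal epithelial identity, mitosis, DNA replication, immediate early genes, NF-kB targets, hypoxia and glycolysis, sterol synthesis, aryl hydrocarbon receptor targets, the BCL2 family, interferon response, proteasome subunits, ribosome biogenesis, histones, basal and mesenchymal markers, and blood cell markers. Members were also counted after adjustment over the list alone.

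Groups, tests, lists, the alternative analyses and the rule for naming genes were set before the data were examined. The rule names, per response, the 10 largest rises and 10 largest falls among called genes with a symbol whose treated arrays all lie on the same side of every control array. It names the 6 largest in each direction for the difference of responses and for the untreated sets, and up to 4 members per list with the largest absolute change in each response. ESR1, HMOX1, CDKN1A and MYC were named whatever their values. A fold change is given as "at least" where the gene was not well above background on any array of the lower group. For that bound, the gene's value on each such array was raised to the lowest value of any gene well above background there, where it lay below it. The difference of the responses and that of the untreated sets were bounded in the same way.

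The alternative analyses set then were quantile normalization, median centring, normexp background correction (offset 50), no filter, a filter on all arrays, each probe on its own, a replicate block, slide as a random block, a trended and robust variance, only the arrays compared, the deposited table, all 6 untreated arrays as control, the 2 compounds compared directly, and leaving out each array. The deposited table was divided by its 75th percentile and floored at 0.02 before log2. Normexp used the median spot intensity, since the files hold no mean. Chosen after seeing the data were cyclic loess, scaling to 8 spike-in probes, averaging of near-identical arrays, and the brighter genes without plumbagin control 3.

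Replicate arrays differed by a median of 0.047 to 0.459 on the log2 scale. The closest pairs were acetyl plumbagin 2 and 3 (0.047), acetyl plumbagin controls 1 and 2 (0.06) and plumbagin 1 and 2 (0.064). For probes with 10 repeated spots, an F ratio set the variation of the array difference between probes against that among spots of a probe. It was 1.49, 5.68 and 11.1 for the plumbagin, acetyl plumbagin and control pairs and 95 to 590 for the others. This ratio scales with the spots per probe. For the closest pairs, in that order, the SD between probe means was 0.046, 0.058 and 0.08, against 0.116, 0.076 and 0.075 among spots. The arrays of these closest pairs were kept apart in the tests, and averaged as an alternative. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.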

Results

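Plumbagin is a naphthoquinone that carries a hydroxyl group, and in acetyl plumbagin that hydroxyl carries an acetyl ester. The series profiled gene expression in MCF-7 cells 6 h after each compound at 10 µM, each beside its own untreated set. The plumbagin arrays were far dimmer than the rest: their 75th percentile signals were 147 and 139, against 833 to 1778.5 on the 3 plumbagin controls, 971 to 1109.5 on the 3 acetyl plumbagin arrays and 630 to 1288.5 on the 3 acetyl plumbagin controls. Of the 33879 probes with a value on every array, 51.4% and 48.5% were well above background on the 2 plumbagin arrays. The share was 64.5% to 67.5% on the acetyl plumbagin arrays and 57.1% to 60.1% on the acetyl plumbagin controls. On plumbagin controls 1, 2 and 3 it was 60.9%, 64.7% and 95.5%. No array had a saturated probe. Each treated group filled a slide of its own, while 4 control arrays shared a slide (the 3 acetyl plumbagin controls and plumbagin control 3) and plumbagin controls 1 and 2 shared another. Treatment and slide therefore cannot be told apart in these data.

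**Figure D1:**
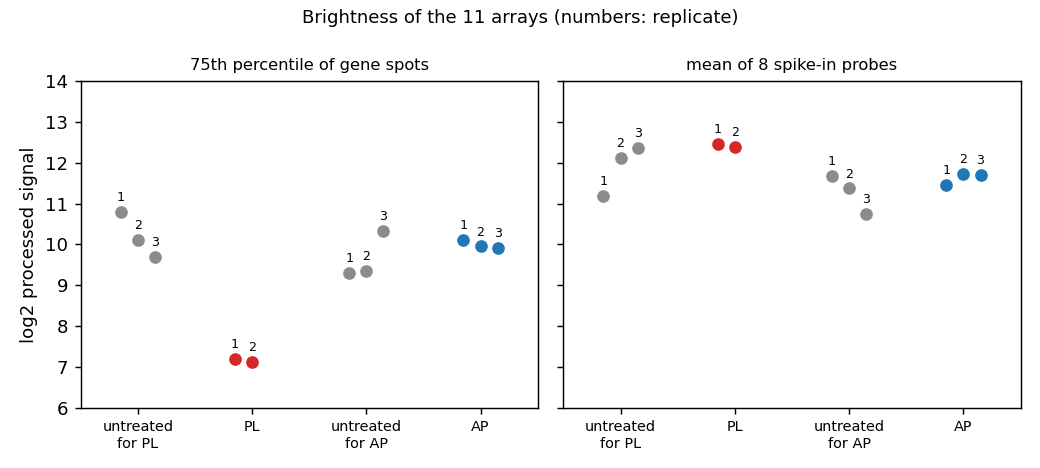
Left, log2 of the 75th percentile of gene spot signals for each array (points) by group; right, mean log2 signal of 8 spike-in probes for the same arrays. The 2 plumbagin arrays had the lowest 75th percentiles (7.2 and 7.12) and a mean spike-in signal of 12.43, above the means of the other 3 groups.

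With acetyl plumbagin, genes of electrophile and xenobiotic stress were among those that rose. HMOX1, which encodes the haem-degrading enzyme heme oxygenase 1, rose by 3.40 ± 0.20 on the log2 scale (SE, 3 treated against 3 control arrays, limma adjusted p = 0.000119), or 10.6-fold. CYP1A1, the cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 2.82 ± 0.15 (adjusted p = 8.41e-05), or 7.05-fold. ATF3, a stress-induced transcription factor, rose by 1.19 ± 0.12 (adjusted p = 0.000649), and SLC7A11, the cystine importer that feeds glutathione synthesis, rose by 1.19 ± 0.22 (adjusted p = 0.00747). The cytokine gene LIF rose by 1.84 ± 0.13 (adjusted p = 0.000168). All 3 treated arrays lay above all 3 control arrays for HMOX1 and CYP1A1.

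Across the genome 3960 of 17648 genes passed the test with acetyl plumbagin, 2161 higher and 1799 lower, with 486 and 684 of them by 2-fold or more. At an unadjusted p under 0.05 the count was 6407. Among the largest rises, TBX1, a developmental transcription factor, rose by 6.15 ± 0.44 (limma adjusted p = 0.000168), EXOC3L1 by 5.75 ± 0.42, KRT78, an epithelial keratin, by 4.66 ± 0.22 (adjusted p = 5.29e-05), PANX2 by 4.51, TUSC1 by 4.25 ± 0.29, CEL by 3.87 ± 0.31 and NCF1 by 3.45. SILC1 was at least 13.5-fold higher, TMEM108 at least 6.06-fold and POM121L10P at least 5.12-fold, all 3 well above background on no acetyl plumbagin control. The largest falls were in LRRD1 (−5.74 ± 0.42, adjusted p = 0.000168, well above background on 2 of 3 treated arrays), MED29 (−3.64; 2 of 3 treated arrays), KCNQ2, a potassium channel gene (−3.42 ± 0.35), RPS10P7 (−3.19), PPP6R1 (−3.13; 2 of 3 treated arrays), the ribosomal protein gene RPS12 (−3.11 ± 0.42), IL18RAP (−3.07), KIAA1958 (−3.01; 1 of 3 treated arrays) and FAM111B (−3.01). TRIM23 was at least 4.8-fold lower, except that normexp background correction turned its value to 0.27. Of these, POM121L10P was not called without acetyl plumbagin 2 or acetyl plumbagin control 1 or 3 (3.56 to 3.77 on the log2 scale), and TMEM108 not without acetyl plumbagin 2 or acetyl plumbagin control 2 (3.82 to 3.85). PPP6R1 was not called without acetyl plumbagin 1 or 2, either plumbagin array or any 1 acetyl plumbagin control (−3.33 to −2.50).

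Among NRF2 targets, the genes of the antioxidant response, 9 rose, 3 fell and 14 did not pass the test with acetyl plumbagin (median 0.37, camera adjusted p = 0.003, adjusted p = 0.361 with an estimated correlation). HMOX1 and AKR1B10 (1.51) were among those that rose, and UGDH was among those that fell (−1.49). Adjusted over the list alone, 12 rose and 3 fell. With normexp background correction this list was not past the test. Of the 6 aryl hydrocarbon receptor targets, 4 rose and none fell (median 0.94, camera adjusted p = 0.00257, adjusted p = 0.221 with an estimated correlation), among them TIPARP, a feedback repressor of the receptor (1.09), and CYP1A2 (0.78). This list call was lost when genes had to be well above background on all arrays.

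Immediate early genes, which respond within minutes to growth factors and stress, rose as a group with acetyl plumbagin: 8 rose, none fell and 12 did not pass (median 0.78, camera adjusted p = 6.8e-05, adjusted p = 0.221 with an estimated correlation). The growth factor gene HBEGF rose by 1.29 ± 0.14 (limma adjusted p = 0.000845) and MYC, a growth-promoting transcription factor, by 0.91 ± 0.20 (adjusted p = 0.0153). MYC was not called without acetyl plumbagin 2 (0.87) or 3 (0.89) or without acetyl plumbagin control 1 (0.88) or 2 (0.88). Of 13 NF-kB targets 4 rose and none fell (median 0.84, camera adjusted p = 0.003, adjusted p = 0.232 with an estimated correlation), and 5 rose adjusted over the list alone. Of 12 interferon response genes 5 rose and none fell (median 0.61, camera adjusted p = 0.00799, adjusted p = 0.388 with an estimated correlation), RIGI, a sensor of viral RNA, by 1.51. The interferon call was lost with quantile normalization and with only the arrays compared.

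ATF4 targets, the amino acid and endoplasmic reticulum stress arm, had 6 genes higher, 1 lower and 14 not past the test with acetyl plumbagin (median 0.37, camera adjusted p = 0.0336, adjusted p = 0.549 with an estimated correlation). CHAC1, which degrades glutathione, rose by 1.73 ± 0.16 (limma adjusted p = 0.000452) and DDIT4, an inhibitor of mTOR signalling, by 1.02. In the BCL2 family of apoptosis regulators 4 of 14 rose and none fell (median 0.28, camera adjusted p = 0.0336, adjusted p = 0.451 with an estimated correlation). Both calls were lost without acetyl plumbagin 3 (medians 0.33 and 0.25), without acetyl plumbagin control 3 (0.27 and 0.26) and without plumbagin control 3 (0.37 and 0.28). They were also lost with cyclic loess, normexp, quantile normalization, only the arrays compared or a filter on all arrays. The adjusted p over alternatives ranged from 0.000765 to 0.549 for ATF4 targets and from 0.000765 to 0.451 for the BCL2 family.

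The other 15 lists did not pass the test with acetyl plumbagin. For p53 targets 6 rose and 1 fell (median 0.22, camera adjusted p = 0.0647), with GDF15 (1.14) and GADD45A (1.06) higher, while CDKN1A, the p53-induced cell cycle inhibitor, had a value of 0.45 ± 0.25 (limma adjusted p = 0.243). Among oestrogen-induced genes 2 rose and 6 fell (median −0.02), GREB1, a cofactor of the oestrogen receptor, by −1.46 ± 0.30 (adjusted p = 0.0113). ESR1, the receptor gene, had a value of −0.34 ± 0.24 (adjusted p = 0.352). Heat shock chaperones had 7 genes lower and none higher (median −0.01), and endoplasmic reticulum chaperones 3 lower and none higher, SEL1L by −2.07 ± 0.21 (adjusted p = 0.000654). Metallothioneins had 2 higher (median 0.27), luminal identity 1 higher and 1 lower (−0.14), mitosis 2 lower (−0.19), DNA replication 3 higher and 2 lower (−0.01), hypoxia and glycolysis 3 and 3, and sterol synthesis 2 higher and 3 lower. Proteasome subunits had 4 higher and 2 lower (−0.20), ribosome biogenesis 3 higher and 4 lower (−0.14), histones 1 lower (−0.29), basal and mesenchymal markers none (0.20), and blood cell markers 1 higher (0.49).

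List medians near 0 changed sign with scaling for acetyl plumbagin. Endoplasmic reticulum chaperones had a median of 0.07 and −0.10, −0.05 and −0.07 with normexp, quantile and cyclic loess. Sterol synthesis had 0.03 and −0.07, −0.08 and −0.09, and hypoxia and glycolysis 0.03 and, with quantile and cyclic loess, −0.04 and −0.06. The mean of the endoplasmic reticulum chaperones (−0.13) and of sterol synthesis (−0.04) had the opposite sign to their medians, and the direction of the camera test for DNA replication was up against a median of −0.01.

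The acetyl plumbagin count rested on single arrays. It was 1141 without acetyl plumbagin 2, 1665 without acetyl plumbagin 3, 1479, 1625 and 2327 without acetyl plumbagin controls 1, 2 and 3, and 7969 without plumbagin control 3, which enters through the shared spread. With slide as a random block 6 genes were called, TBX1, EXOC3L1, KRT78 and CEL among them (adjusted p = 0.0486 each), while HMOX1 (adjusted p = 0.117) and CYP1A1 (adjusted p = 0.0566) were not. The correlation within slides behind that block rests on plumbagin control 3, since only the plumbagin controls lay on more than 1 slide. With near-identical arrays averaged 65 genes were called, HMOX1 and CYP1A1 among them (adjusted p = 0.0374 each). Over all alternatives the adjusted p ranged from 4.36e-06 to 0.117 for HMOX1, from 2.47e-06 to 0.0566 for CYP1A1, and from 3.96e-06 to 0.0486 for TBX1. Of the 88 named genes called here, 44 kept the call without each array in turn: 44 lost it without acetyl plumbagin 2, 31 without 3, 7 without 1, 37, 33 and 22 without acetyl plumbagin controls 1, 2 and 3, 18 without either plumbagin array, and 3 without plumbagin control 2.

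With plumbagin, CYP1A1 moved in the opposite direction. It fell by 5.73 on the log2 scale (SE 0.16, 2 treated against 3 control arrays, limma adjusted p = 1.34e-06), at least 50.8-fold lower, since it was well above background on no plumbagin array. SLC7A11 fell by 3.50 (SE 0.24, adjusted p = 9.69e-05), at least 7.2-fold. ATF3 fell by 1.28 (SE 0.14, adjusted p = 0.000396), LIF by 1.35 (SE 0.14) and FOXK1, a forkhead transcription factor, by 3.31 (SE 0.15, adjusted p = 3.32e-05). H3C15, a histone H3 gene, rose by 4.27 ± 0.47 relative to the 75th percentile (adjusted p = 0.000455). HMOX1 had a value of −0.15 ± 0.23 (adjusted p = 0.662).

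**Figure D2:**
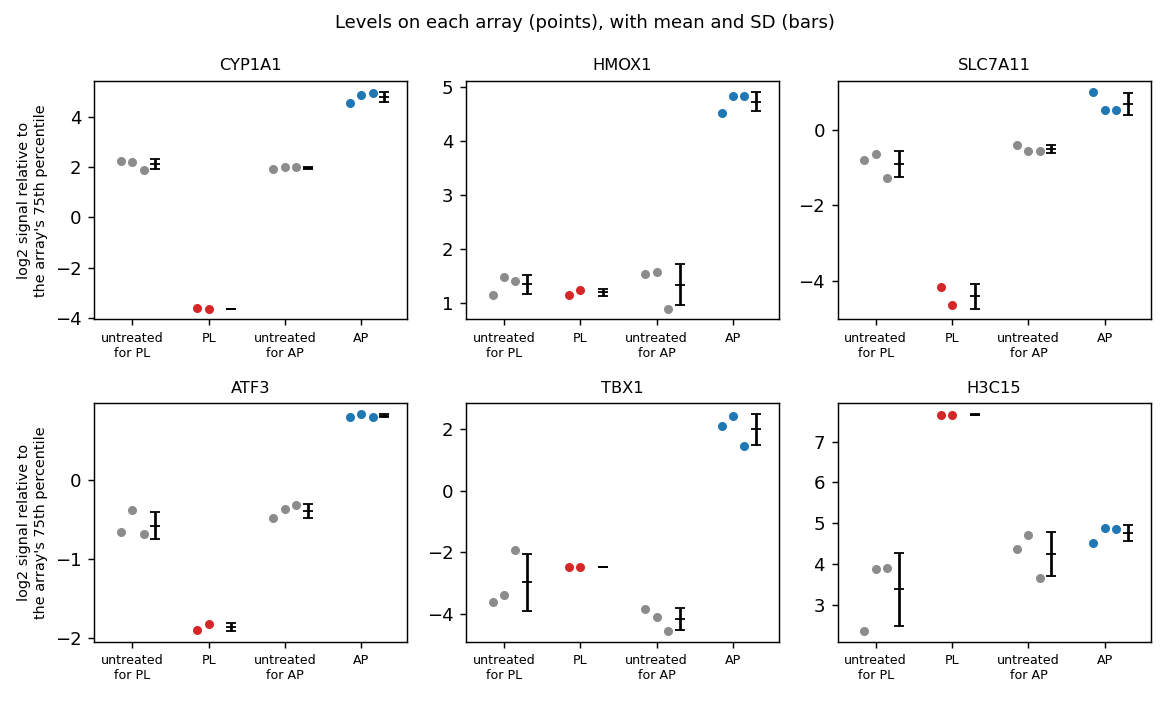
Levels of 6 genes on each array (points, log2 relative to the 75th percentile of the array) with the mean and SD of each of the 4 groups. CYP1A1 averaged −3.63 on the plumbagin arrays and 4.78 on the acetyl plumbagin arrays, against 2.11 and 1.96 on their controls, and H3C15 averaged 7.66 on the plumbagin arrays against 3.38 on their controls; scaled to the spike-in probes, each plumbagin change shifts by −3.59.

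With plumbagin 5773 of 17648 genes passed the test, 3265 higher and 2508 lower, with 1762 and 1296 by 2-fold or more and 7580 at an unadjusted p under 0.05. These directions are relative to the 75th percentile of each array. Scaled to the spike-in probes the median of all genes moved to −3.58, with 5 genes higher and 17140 lower, so that every rise under plumbagin smaller than 3.59, histones as a list included, turns into a fall. With normexp background correction the median of all genes was 0.55, with 884 higher and 279 lower, and with only the arrays compared 1163 were higher and 486 lower. With normexp the median was 0.27 for acetyl plumbagin and 0.42 for the difference of the responses, and with quantile normalization that of the untreated sets was −0.15.

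The largest rises with plumbagin, relative to the 75th percentile, were in CD86, an immune costimulator gene (8.12 ± 1.64, limma adjusted p = 0.00584, well above background on 1 of 3 controls), GPR179 (5.95; 1 of 3 controls), SPEN, a transcriptional repressor (4.94 ± 0.60, adjusted p = 0.000631), KRT79 (4.67; 1 of 3 controls), the non-coding RNA genes RMRP (4.32 ± 0.41, adjusted p = 0.000278), SNORA28 (4.32 ± 0.64), RNA5-8SN5 (4.24) and RN7SK (3.90 ± 0.70), H3C15, and HAPLN2 (4.04). Beside CYP1A1, SLC7A11 and FOXK1, the named falls were SRF, which drives serum response genes (at least 4.08-fold; −0.12 with normexp), and MED31, INPP1, LUZP1, C2CD2, FOXJ2 and TCEANC2. MED31 was at least 1.93-fold lower, INPP1 2.74, LUZP1 2.05, C2CD2 2.18, FOXJ2 2.39 and TCEANC2 2.3, and normexp turned all 6 to rises of 0.43, 0.21, 0.45, 0.60, 0.50 and 0.40. GPR179, KRT79, HAPLN2, RNA5-8SN5 and MED31 were not called without plumbagin 1 or plumbagin 2. GPR179 was also not called without plumbagin control 1 or 2 (4.83 to 6.10 over the arrays named), nor KRT79 without plumbagin control 2 (3.84 to 4.99), nor MED31 without plumbagin control 1 (−3.21 to −2.33). HAPLN2 ran from 3.93 to 4.16 without plumbagin 1 or 2. Its plumbagin controls 1, 2 and 3 read −2.27, 1.93 and 1.97, so the size of its rise leans on control 1. RNA5-8SN5 was also not called without plumbagin control 1, any 1 acetyl plumbagin array or acetyl plumbagin control 1 or 2 (2.68 to 4.25). The sizes of the rises of RNA5-8SN5, SNORA28, RN7SK and H3C15 lean on plumbagin control 1 as well. It read −2.94 for RNA5-8SN5 against 1.64 and 1.83 on controls 2 and 3, −2.24 for SNORA28 against 0.1 and 0.06, and 2.36 for H3C15 against 3.89 and 3.91.

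Of 14 histone genes 12 rose, none fell and 2 did not pass with plumbagin (median 1.39, camera adjusted p = 5.84e-05, adjusted p = 0.738 with an estimated correlation), with medians of 1.03, 0.86 and 1.06 under normexp, quantile and cyclic loess. H3C2 rose by 2.83 ± 0.47 and H4C3 by 2.27 ± 0.27. Of 6 aryl hydrocarbon receptor targets 3 fell and none rose (median −0.96, camera adjusted p = 0.0195, adjusted p = 0.738 with an estimated correlation), among them CYP1B1 (−0.94). CYP1A2 fell too (−1.02, at least 1.25-fold), except with normexp (1.27). This list was not past the test when genes had to be well above background on all arrays.

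Immediate early genes fell with plumbagin: 7 fell, none rose and 13 did not pass (median −0.51, camera adjusted p = 0.0266, adjusted p = 0.738 with an estimated correlation). CCN1, a matricellular growth regulator, fell by 1.33 and MYC by 0.97 (SE 0.22, limma adjusted p = 0.0107), while HBEGF was well above background on no plumbagin array and its probe bounds no fall there (1.43 with normexp). The list was not past the test without plumbagin control 1 (median −0.32, adjusted p = 0.0973), against a range of 0.00419 to 0.738 over alternatives. MYC was not called without plumbagin 1 (−0.96) or 2 (−0.98). Of 21 ATF4 targets 9 fell and none rose (median −0.33, camera adjusted p = 0.0266, adjusted p = 0.738 with an estimated correlation), or 9 and 1 adjusted over the list alone. SESN2, a stress-induced inhibitor of mTOR signalling, fell by 1.42 (SE 0.18, adjusted p = 0.000728) and DDIT4 by 1.01.

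The other 18 lists did not pass the test with plumbagin. NRF2 targets had 5 higher and 3 lower (median 0), with FTH1, the ferritin heavy chain (1.65), and GSR, glutathione reductase (1.37), higher. For p53 targets 4 rose and 8 fell (median −0.40, 0.06 with normexp), TP53INP1 by −1.75, and CDKN1A had a value of −0.69 ± 0.28 (limma adjusted p = 0.0967). Oestrogen-induced genes had 6 higher and 4 lower: CA12, a carbonic anhydrase, fell by 1.18 and TFF1, a secreted mucosal peptide, rose by 1.27 but had −0.60 and −0.10 with quantile and cyclic loess. In luminal identity 4 rose and 6 fell: KRT18 rose by 2.59 ± 0.29 and KRT8 by 2.08 ± 0.18, both epithelial keratins, and ESR1 fell by 1.19 (SE 0.27, adjusted p = 0.00977). ESR1 was not called without plumbagin 1 (−1.21) or plumbagin 2 (−1.17). BCL2 family genes had 4 higher and 3 lower (0.49), with BMF, a promoter of apoptosis, at least 5.47-fold lower and BCL2L1, an inhibitor of it, at −1.50. NF-kB targets had 2 lower (−0.22; 0.76 with normexp), BIRC3 among them at least 1.29-fold, though 1.00 higher with normexp.

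Endoplasmic reticulum chaperones had 7 higher and 2 lower with plumbagin (median 0.34; −0.03 with quantile normalization), CANX, which folds glycoproteins, by 2.87 ± 0.49. Ribosome biogenesis had 9 higher and 1 lower (0.38; −0.12 and −0.03 with quantile and cyclic loess), and proteasome subunits 10 higher and 1 lower (0.21; −0.17, −0.33 and −0.30 with normexp, quantile and cyclic loess). Heat shock chaperones had 7 higher and 3 lower (−0.10; 0.13 with normexp), metallothioneins none (0.31; −0.19, −0.41 and −0.42), and mitosis 3 higher and 1 lower (0.06; −0.16, −0.14 and −0.11), MKI67 by 1.95 ± 0.32. DNA replication had 3 higher and 2 lower (0.10; −0.13, −0.26 and −0.22), and hypoxia and glycolysis 3 higher and 5 lower (0.10; −0.38 and −0.37 with quantile and cyclic loess). Sterol synthesis had 2 higher and 3 lower (−0.13), interferon response 2 and 2 (0.14), basal and mesenchymal markers 2 lower (0.51) and blood cell markers 2 higher (0.24). The luminal median of 0.09 turned to −0.36, −0.69 and −0.66 and the oestrogen-induced median of 0.07 to −0.04 and −0.14 with quantile and cyclic loess. The mean had the sign opposite to the median for heat shock (0.07), DNA replication (−0.04), hypoxia and glycolysis (−0.03) and interferon response (−0.08). The camera test pointed down for basal markers and hypoxia and up for heat shock, DNA replication and interferon response.

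**Figure D3:**
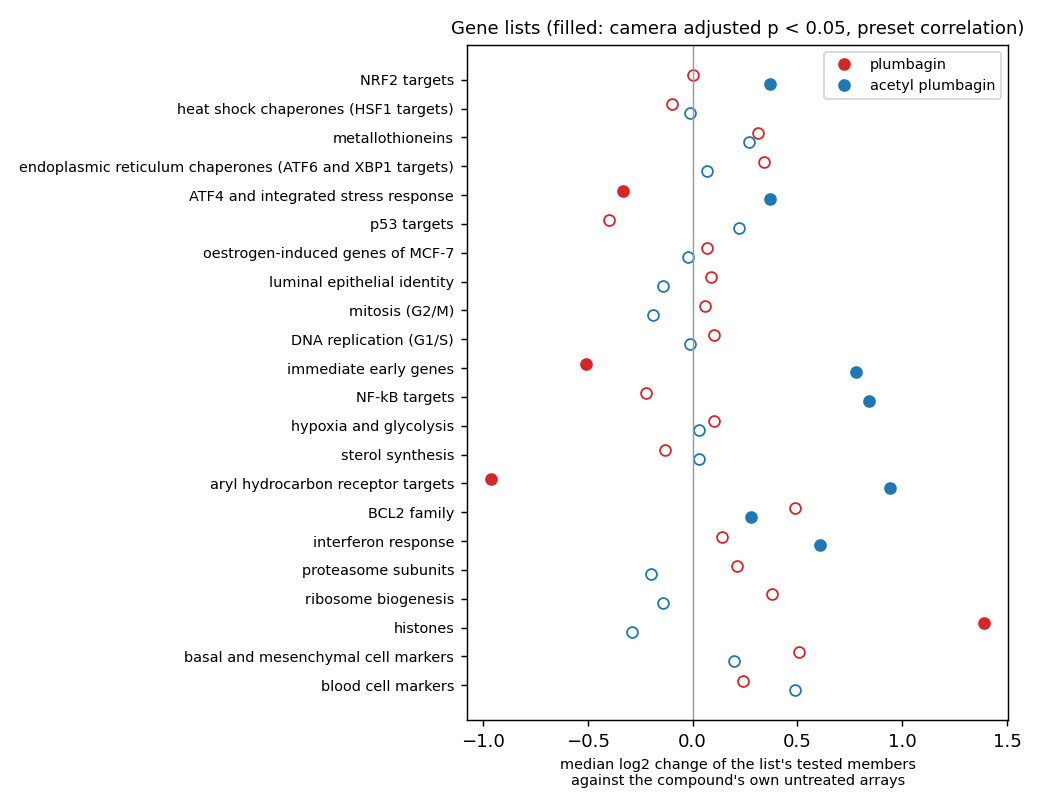
Median log2 change of the tested members of 22 gene lists with plumbagin (red) and acetyl plumbagin (blue), each relative to the 75th percentile of the array; filled points passed the camera test at the preset correlation. With plumbagin the histone median was 1.39 and the aryl hydrocarbon receptor median −0.96, against −0.29 and 0.94 with acetyl plumbagin, and scaling to the spike-in probes would shift every plumbagin point by −3.59.

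With slide as a random block 37 genes were called with plumbagin, and with near-identical arrays averaged 1 was, CYP1A1 (adjusted p = 0.000506 and 0.0166, range over alternatives 6.8e-09 to 0.0346). Averaging leaves 1 plumbagin value, whose spread is then that of the other groups, and with plumbagin control 3 also left out it gave 5430 genes, 3662 higher and 1768 lower, so that the drop to 1 gene depended on that control. With slide as a block SLC7A11 (adjusted p = 0.047, range 8.53e-06 to 0.228) and FOXK1 (adjusted p = 0.0158, range 8.69e-07 to 0.063) also stayed past the test. The count was 2939 without plumbagin 1, 2669 without plumbagin 2 and 9787 without plumbagin control 3. Of the 119 named genes called, 75 kept the call without each array in turn: 40 lost it without plumbagin 1, 38 without plumbagin 2, 10 and 8 without plumbagin controls 1 and 2, 2, 5 and 5 without acetyl plumbagin 1, 2 and 3, and 6, 6 and 1 without acetyl plumbagin controls 1, 2 and 3.

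The responses to the 2 compounds at the same dose and time were compared by testing their difference, plumbagin minus acetyl plumbagin. HMOX1 differed by −3.55 (95% confidence interval −4.24 to −2.87), ATF3 by −2.47 (−2.89 to −2.06), LIF by −3.19 (−3.63 to −2.75) and MYC by −1.88. CYP1A1 (limma adjusted p = 5.28e-07), SLC7A11 and HBEGF were well above background on no plumbagin array, so their differences are only bounded: −8.48, −4.04 and −1.04 or further from 0. In the other direction KRT18 differed by 3.47 and LRRD1 by 8.22 (6.80 to 9.65, adjusted p = 0.00025). For some genes the difference did not pass the test, which does not show that they responded alike: RET differed by 0 (−0.52 to 0.52, adjusted p = 0.996), TXNRD1, thioredoxin reductase, by 0.16 (−0.75 to 1.07, adjusted p = 0.805) and RRP9, a ribosomal RNA processing factor, by 0.08 (−0.48 to 0.63).

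The difference passed the test for 4960 genes, 2742 higher with plumbagin and 2218 lower, with 7029 at an unadjusted p under 0.05. Lists lower with plumbagin were immediate early genes (median −1.01, 8 lower, none higher, camera adjusted p = 2.65e-05), aryl hydrocarbon receptor targets (−1.77, 4 lower, 0.000445), NF-kB targets (−0.94, 5 lower, 8 adjusted over the list alone, 0.00165), ATF4 targets (−0.36, 7 lower, 1 higher, 0.00165) and p53 targets (−0.61, 8 lower, 0.0483). Histones were higher (1.66, 12 higher, 2.65e-05), and so were proteasome subunits (0.37, 10 higher, 2 lower, 0.0408) except that the direction of the test turned with cyclic loess (0.009), normexp (0.087) and quantile normalization (−0.11). None of the list calls in any of the 3 comparisons held with an estimated correlation, where the smallest adjusted p of this comparison was 0.152. The other 15 lists did not pass, with adjusted p of 0.0717 for ribosome biogenesis and 0.0729 for NRF2 targets (−0.38) and endoplasmic reticulum chaperones (0.25). The p53 call was lost without acetyl plumbagin 2 (−0.57) or 3 (−0.56), plumbagin 1 (−0.60), acetyl plumbagin control 2 (−0.66) or plumbagin control 1 (−0.62) or 2 (−0.60), and the proteasome call without acetyl plumbagin 3 (0.37) or plumbagin control 3 (0.29). Both calls were also lost with median centring, near-identical arrays averaged or a filter on all arrays, the p53 call with the deposited table, and the proteasome call with no filter or the replicate block. The aryl hydrocarbon receptor call was lost with the filter on all arrays (−1.34).

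The count of differing genes was 48 with slide as a random block, with CYP1A1, SLC7A11, ATF3, LIF and HBEGF among them, 1 with near-identical arrays averaged (CYP1A1, from 1 plumbagin value), 855 with normexp (612 higher, 243 lower) and 15678 with spike-in scaling (16 higher, 15662 lower). It was 2819 without plumbagin 1, 2725 without plumbagin 2 and 8930 without plumbagin control 3.

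The 2 responses shared 887 called genes in the same direction. Both higher held for 667 genes, against 400 for independent lists (Fisher exact p = 2.92e-50), and both lower for 220 against 256 (exact p = 0.0103). Higher with plumbagin and lower with acetyl plumbagin held for 410 against 333 (exact p = 1.49e-06), and the reverse for 321 against 307 (exact p = 0.357). Without plumbagin control 3 the excess of both higher shrank (1618 against 1458.7, odds ratio 1.24, from 2.21), both lower held for 690 against 787.3 and the reverse for 856 against 906.5. The excess of higher with plumbagin and lower with acetyl plumbagin was then 1294 against 1266.8 (exact p = 0.293). Genes are not independent, so these p-values overstate the evidence. Both responses were also tested against 1 shared spread per gene, so a gene with a small spread can be called in both, which independent lists leave out. Across all genes the log2 changes had a Pearson correlation of −0.074, and 0.324 with normexp; the responses share no control array. The same-direction count was 224 and 309 without acetyl plumbagin 2 and 3, 321 and 282 without plumbagin 1 and 2, 315, 356 and 450 without acetyl plumbagin controls 1, 2 and 3, and 2308 without plumbagin control 3.

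The 2 untreated sets, both of MCF-7 cells without compound, differed at 9 of 17648 genes, all higher in the plumbagin controls (limma, 2262 at an unadjusted p under 0.05). The 5 with a symbol were well above background on no acetyl plumbagin control: GALNTL5 was at least 4.59-fold higher (adjusted p = 0.0229), EGFL6 3.71 (adjusted p = 0.00169), LRIT3 2.35 (adjusted p = 0.0318), SLC4A5 2.25 (adjusted p = 0.00234) and LDLRAD3 1.85 (adjusted p = 0.0153). With cyclic loess 18 genes were higher and 3 lower, and with slide as a random block 6847 differed. The slide count leans on plumbagin control 3, the array that stands apart, so it is no measure of how the sets differ. The count was 20, 179 and 69 without plumbagin controls 1, 2 and 3, and 5 without acetyl plumbagin 1 or any 1 acetyl plumbagin control. The sets share a slide only through plumbagin control 3, a single array, so they could not be compared within a slide with replicates on both sides.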

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

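Of the tests weighed here, the 3 on the dim plumbagin arrays and the one for an added background were chosen only after those patterns were seen, as was the spread given for the brightness prediction, and the others were written beforehand.

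By the test of the difference itself (limma, n = 2 or 3 per group), the responses to the 2 compounds differed at 4960 genes, in size or in direction. The largest differences toward plumbagin were in CD86 (10.25), LRRD1 (8.22), GPR179 (8.05), RNA5-8SN5 (6.93), PPP6R1 (6.36) and SPEN (5.90). CD86 was well above background on only 1 of 3 plumbagin controls and 1 of 3 acetyl plumbagin arrays, so the size of its difference is uncertain. The largest toward acetyl plumbagin were in CYP1A1 (−8.55), TBX1 (−5.64), LGI3 (−5.26), PANX2 (−5.17), POM121L10P (−4.75) and SILC1 (−4.74). These are fitted values, and 6 of the 12 are only bounded. CYP1A1, LGI3, PANX2, POM121L10P and SILC1 were well above background on no plumbagin array, the last 2 on no acetyl plumbagin control either, and GPR179 on no acetyl plumbagin array. With those arrays raised to the background limit the differences were −8.48, −4.65, −5.14, −1.45, −2.68 and 5.94. The POM121L10P bound leans on plumbagin control 3, the array that stands apart, which read −2.2 against −5.91 and −5.84 on controls 1 and 2. PANX2 and SILC1 were also highest on that control among the plumbagin controls. Without single arrays 3 of these 12 calls were lost. GPR179 lost its call without any 1 acetyl plumbagin array, either plumbagin array, acetyl plumbagin control 2 or plumbagin control 2 (7.11 to 8.20). RNA5-8SN5 lost it without acetyl plumbagin 2 or 3, either plumbagin array or acetyl plumbagin control 1 or 2 (6.41 to 6.95). POM121L10P lost it without acetyl plumbagin 1 or 2, either plumbagin array or acetyl plumbagin control 1 (−4.86 to −4.52). With slide as a random block 9 of the 12 were not past the test, and with near-identical arrays averaged, which leaves 1 plumbagin value, 11 were not.

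Among gene lists the difference passed the test for ATF4 targets (−0.36), p53 targets (−0.61), immediate early genes (−1.01), NF-kB targets (−0.94), aryl hydrocarbon receptor targets (−1.77), proteasome subunits (0.37, but turned with quantile normalization, −0.11, cyclic loess, 0.009, and normexp, 0.087) and histones (1.66). Each value is the median of plumbagin minus acetyl plumbagin. None of the 7 passed with an estimated correlation (adjusted p = 0.152 to 0.851). The p53 call was lost without acetyl plumbagin 2 (−0.57) or 3 (−0.56), plumbagin 1 (−0.60), acetyl plumbagin control 2 (−0.66) or plumbagin control 1 (−0.62) or 2 (−0.60). The proteasome call was lost without acetyl plumbagin 3 (0.37) or plumbagin control 3 (0.29). Both were also lost with median centring, near-identical arrays averaged or a filter on all arrays, the p53 call with the deposited table, and the proteasome call with no filter or the replicate block. The aryl hydrocarbon receptor call was lost with the filter on all arrays (−1.34).

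The first pattern weighed was the low signal of the plumbagin arrays. The spike-in probes, which the comparisons do not use, were brighter by 0.55 on the plumbagin arrays than on their controls, so a loss of signal across the whole array does not explain it. Structural non-coding RNA lay 3.03 above protein-coding genes of matched brightness (adjusted p = 0.223 by limma camera with an estimated correlation, n = 2 or 3). This gap argues against too little RNA labelled with all kinds of RNA lost alike, but does not rule it out. The set was chosen after seeing the data and includes some of the largest rises it is tested on. Structural non-coding RNA and histones together, transcripts largely without a poly(A) tail, lay 2.01 above matched genes with plumbagin (adjusted p = 0.223 by limma camera with an estimated correlation, n = 2 or 3) and −0.37 with acetyl plumbagin. A candidate explanation is that plumbagin left fewer polyadenylated transcripts per amount of total RNA. Less transcription or RNA decay in these samples could each do so, and these data cannot separate either from the slide. Per the labels, 1 further plumbagin RNA was left out because its integrity was poor. Whether RNA integrity plays a part on the plumbagin arrays kept was not tested. Array brightness was not weighed for this pattern. RMRP, SNORA28, RNA5-8SN5, RN7SK and H3C15 also ran lower on a brighter array without compound, acetyl plumbagin control 3, than on controls 1 and 2. RN7SK read 4.23 there against 5.4 and 5.55, and RNA5-8SN5 0.41 against 3.43 and 3.5. Among the plumbagin controls all of these were lowest on control 1, the brightest array (75th percentile 1778.5), which enters the plumbagin contrast. RN7SK read 2.35 on it against 4.96 and 4.52 on controls 2 and 3, and RNA5-8SN5 −2.94 against 1.64 and 1.83. Array brightness therefore stays open as a cause of their rise.

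The second pattern was plumbagin control 3, on which 95.5% of probes were well above background and the lowest spike-in probe read 191.3, against 2.3 to 8.1 elsewhere. Its median excess over plumbagin controls 1 and 2 was 2.68 in the dimmest of 5 brightness classes, then 0.94, 0.05, −0.27 and −0.31 in the brightest. A first test on these classes left an added background open, but raw signal at 153 negative control spots rose by only 0.15 of the rise of the dimmest genes (0.25 at the 95th percentile of those spots), which argues against a background on every probe. An addition limited to probes other than the negative controls was not tested, and the raised lowest spike-in probe leaves it open. The position of the array between untreated (0) and treated (1) was 0.19 toward plumbagin and −0.08 toward acetyl plumbagin. This argues against a treated sample like those measured here under an untreated label. A partial or mixed sample was not tested, and the measure takes no account of the excess by brightness given above.

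The third pattern was the lack of a shared direction over all genes, with a correlation of −0.074 (jackknife SD 0.091, and 0.324 with normexp). Even so, 667 genes were higher with both against 400 for independent lists. That excess shrank without plumbagin control 3 (1618 against 1458.7, odds ratio 1.24, from 2.21). Array brightness may contribute to the lack of a shared direction: the difference between bright and dim untreated arrays correlated with the plumbagin response at −0.345 across genes. Scaled to the brightness gap of the plumbagin arrays, it predicted a median change of −0.12 for 39 immediate early, NF-kB and aryl hydrocarbon receptor genes, against −0.60 observed (−0.08 with normexp, where all genes had 0.55 in place of 0.01). Members resampled, that prediction ran from −0.52 to 0.44, and it stretched a gap of 1.00 on 1 bright array to −3.04, so brightness stays open as the cause of their fall. Transcripts known to be short-lived had a median of −0.66 with plumbagin (−0.12 with normexp, also below the 0.55 of all genes), at percentile 0 of 10000 random lists of matched brightness, the lowest of which had −0.58, and 0.25 with acetyl plumbagin, but the list call was lost with an estimated correlation (limma camera adjusted p = 0.00108, then 0.223), so a block of transcription by plumbagin is no more than a candidate explanation.

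Regrouping the 6 arrays of a comparison gives 10 splits, so the share of splits with as many called genes cannot go below 0.1. For acetyl plumbagin 1 of 10 splits had as many, the real one, with 3960 genes against at most 0 in any other. Every other split mixed treated and control arrays, which widened the spread within its groups, so low counts there were built in. The real split was also the split by slide, so no conclusion on the compound is drawn from it. For the untreated sets 1 of 10 had as many, the real one, with 9 genes against at most 1.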

How the results depend on the processing

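Cyclic loess, spike-in scaling, the averaging of near-identical arrays and the brighter genes without plumbagin control 3 were chosen after seeing the data, and the other alternatives before. Counts of changed genes moved by more than 1.5 times under several of them, and the cause was not tested unless stated. The plumbagin count of 5773 became 1 with near-identical arrays averaged (but 5430 averaged and without plumbagin control 3), 1163 with normexp, 1649 with only the arrays compared, 37 with slide as a random block and 17145 with spike-in scaling. Leaving out 1 array gave 2669 to 9787. The acetyl plumbagin count of 3960 became 5941 with cyclic loess, 65 averaged, 1665 averaged and without plumbagin control 3, 1777 with no filter, 545 with normexp, 7976 with only the arrays compared, 2404 with the replicate block, 6 with slide and 186 with spike-in scaling. Leaving out 1 array gave 1141 to 7969.

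The count of genes whose responses differ (4960) became 1 averaged, 855 with normexp, 48 with slide and 15678 with spike-in scaling, and 2725 to 8930 without 1 array. The count between the untreated sets (9) became 21 with cyclic loess, 0 averaged, with normexp, with only the arrays compared and with the filter on all arrays, 5 with no filter, 2 with the deposited table, 6847 with slide, 92 with spike-in scaling and 1 with a trended and robust variance. Leaving out 1 array gave 5 to 179. The same-direction overlap (887) became 542 with median centring, 0 averaged and with slide, 286 with no filter, 66 with normexp, 566 with quantile normalization and 412 with the replicate block, and 224 to 2308 without 1 array. The correlation of the responses (−0.074, jackknife SD 0.091) became 0.324 with normexp, −0.229 with no filter and −0.179 with slide, and −0.135 to −0.037 without 1 array. Slide holds each treated group alone, so its random block widens the error of every treatment contrast by construction, with a correlation within slides of 0.765. That correlation rests on plumbagin control 3, the array that stands apart, since no other group lay on more than 1 slide. It therefore does not measure a slide effect apart from that array. Spike-in scaling shifts every plumbagin change by −3.59 by construction. The other alternatives kept these counts within 1.5 times.

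Directions that turned with normexp belonged mostly to genes near background on the plumbagin arrays. With plumbagin they were BIRC3 (1.00), C2CD2 (0.60), CCN2 (0.86), CYP1A2 (1.27), EGFL6 (0.86), EGLN3 (0.44), FOXJ2 (0.50), GALNTL5 (0.87), HBEGF (1.43), IFIT2 (1.08), INPP1 (0.21), KDM3A (1.16), LDLRAD3 (1.54), LGI3 (0.61), LRIT3 (1.37), LUZP1 (0.45), MED31 (0.43), MSMO1 (0.29), PSAT1 (1.58), SILC1 (1.86), SLC4A5 (1.39), SNAI2 (0.81), SPATA18 (0.46), STARD4 (0.68) and TCEANC2 (0.40). With acetyl plumbagin they were EGLN3 (0.049), HSPA4L (0.017) and TRIM23 (0.27). Quantile normalization turned bright genes under plumbagin: CALR (−0.083), CDT1 (−0.05), HSP90AA1 (−0.07), HSPB1 (−0.056), KRT19 (−0.44), MCM7 (−0.18), NPM1 (−0.10), PSMB1 (−0.25), PSMB4 (−0.18), PSMD8 (−0.078) and TFF1 (−0.60). Cyclic loess turned CDT1 (−0.018), HSP90AA1 (−0.044), MCM7 (−0.12), NPM1 (−0.04), PSMB1 (−0.23), PSMB4 (−0.12), PSMD8 (−0.054) and TFF1 (−0.10).

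Without plumbagin control 3 the plumbagin values of CD3E (1.57), HSPA6 (0.56) and TMEM108 (0.96) turned, each the highest of a range over single arrays left out that began at −1.27, −0.97 and −1.04. With all 6 untreated arrays as control LDLRAD3 turned with acetyl plumbagin (−0.23) and with plumbagin (0.13), and SLC4A5 turned with acetyl plumbagin (−0.97). CD3E, HSPA6 and TMEM108 were not called with plumbagin.

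Among lists under plumbagin, normexp turned DNA replication (−0.13), heat shock (0.13), luminal identity (−0.36), metallothioneins (−0.19), mitosis (−0.16) and proteasome subunits (−0.17), quantile normalization turned DNA replication (−0.26), heat shock (−0.19), luminal identity (−0.69) and proteasome subunits (−0.33), and cyclic loess turned proteasome subunits (−0.30). For the difference of the responses, luminal identity turned with quantile normalization (−0.74), and proteasome subunits with cyclic loess (0.009), normexp (0.087) and quantile normalization (−0.11), judged by the direction of the camera test. List results kept direction and side of the test in 458 of the plumbagin alternatives, 445 of the acetyl plumbagin ones and 424 of those for the difference, lost a call in 6, 27 and 25, and gained one in 9, 12 and 9.

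Named genes kept direction and side of the test in 3767 of the plumbagin alternatives, lost the call in 576, gained it in 92 and turned in 48. For acetyl plumbagin these counts were 3791, 544, 143 and 5, and for the difference 204 were kept and 51 lost. Of 119 called genes 113 lost the call with slide under plumbagin and 118 with averaging, and under acetyl plumbagin 84 and 77 of 88. CEL, EXOC3L1, KRT78 and TBX1 under acetyl plumbagin kept the call in every alternative run for named genes, and CYP1A1 under plumbagin in all but the filter on all arrays, which removed it. Where leaving out an array or averaging left 1 plumbagin value, its spread was assumed to be like that of the other groups.

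Arrays of the same number in different groups were not alike after the group means were removed: over 15 pairs the correlation ran from −0.307 to 0.138, so replicate numbers were not treated as pairs. Signal over background limits the plumbagin comparison, with 51.4% and 48.5% of probes well above background, and genes lost to background there have only a bound for their fall.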

Other observations

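The short-lived list was fixed before its values were seen, the other gene sets named here were chosen after seeing the data, and the tests of structural RNA and short-lived transcripts they rest on are given above.

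Structural RNAs rose with plumbagin relative to the 75th percentile. Of 24 small nuclear, small nucleolar, ribosomal and related RNAs with a tested probe, 17 rose, none fell and 7 did not pass with plumbagin (2 arrays against 3, median 3.15, limma camera adjusted p = 1.28e-08, adjusted p = 0.223 with an estimated correlation). The median was 2.62 with quantile normalization, 2.54 with cyclic loess and 3.47 without plumbagin control 3, and relative to the spike-in probes it shifts by −3.59 to below 0. With acetyl plumbagin none of the 24 passed (median −0.26). Set against matched protein-coding genes, these RNAs lay 3.03 higher, so they may have persisted while polyadenylated transcripts were lost. Array brightness was not weighed for this rise and stays open as a cause, since the members named above also ran lower on brighter untreated arrays.

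Among abundant protein-coding genes, 68 of 76 cytosolic ribosomal protein genes rose with plumbagin (median 1.26, camera adjusted p = 1.25e-23, adjusted p = 0.223 with an estimated correlation), but the median was −0.16 with quantile normalization and 0.07 with cyclic loess. With acetyl plumbagin 14 fell (median −0.34, camera adjusted p = 4.01e-05, adjusted p = 0.882 with an estimated correlation). Subunits of mitochondrial complex I had 21 higher and 1 lower of 37 with plumbagin (0.62, but 0 and 0.06 with quantile and cyclic loess) and 10 higher and 3 lower with acetyl plumbagin (0.13). Tubulins and actins had 9 higher and 1 lower of 13 with plumbagin (0.61, but −0.10 and −0.09) and 1 lower with acetyl plumbagin (0.11). Protein-coding genes matched in brightness to the ribosomal, complex I, and tubulin and actin sets had plumbagin medians of 0.96, 0.52 and 0.66. Most of each rise was therefore shared by equally bright genes. Short-lived transcripts had 5 higher and 15 lower of 39 with plumbagin (camera adjusted p = 0.00108, adjusted p = 0.223 with an estimated correlation), 6 higher and 2 lower with acetyl plumbagin.

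Where several probes of a gene were tested they did not always move together. Of 3396 such genes 232 had probes called in both directions with plumbagin and 24 with acetyl plumbagin. In a principal component analysis the first 3 components held 47.1%, 23% and 16.1% of the variance. Plumbagin control 3 lay furthest out on the first, at −151.3, with the other arrays at −67.3 to 52.5. Relative to the spike-in probes the 75th percentile was −5.27 on the plumbagin arrays (SD 0.001), −1.68 on their controls (SD 1.17), −1.63 on the acetyl plumbagin arrays (SD 0.251) and −1.60 on their controls (SD 1.052). Single untreated arrays ran from −2.65 to −0.38.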
